A study of Zea mays with 144 samples.

How the data were processed

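RNA from anthers of the maize inbred line Ky21 was measured on spotted cDNA arrays of 12160 features. Per the labels, 24 RNA pools (6 stages, upper and lower florets, 2 pools each) were made from 1 to 4 individuals with 8 to 20 anthers per tassel, amplified with T7 RNA polymerase, labelled with Cy3 or Cy5 and hybridised in pairs on 48 slides. Each pool was on 4 slides. A pool number of 1 or 2 in the labels divides the pools into 2 sets, and both pools of a slide come from 1 set. Each slide was scanned at low, medium and high intensity. The RNA pool, not the slide or the scan, was taken as the replicate.

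The deposited values were taken as natural log ratios of the channels, centred by the authors near 0 in each scan, with 1 value per feature and scan. The base is not stated and was read from the values. The software of the normalisation is not given in the sources used here, and signals over background are not used here, so that the precision is described by the spread between pools instead. Column medians lay between -0.0253 and 0.0327 on the natural log scale. The log base was checked on values that repeat 3 or more times within each of 47 low scans. A spot at a whole multiple of the floor and its mirror should lie 2 logs of that number apart. Distances between repeated values met this for a number up to 9, within 5e-06, in 63 cases for the natural log, 0 for log2 and 5 for log10. Over 129 other scalings the mean number of matches was 1.50 and the highest 25, at a factor of 0.5. The settings of this check were adjusted after a first attempt gave few matches.

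The labels give the dye of each pool but not the numerator of the ratio. Slides that compare the florets were planned to be turned by the dyes in the labels. The values showed that these slides run one way whatever the dyes. That way is upper over lower floret if the stage slides are Cy5 over Cy3. They were used as deposited, a choice made after seeing the values. The planned reading is kept as an alternative. A step between stages in upper minus lower florets should equal the floret difference at the later minus that at the earlier stage. In 10 such closed squares the sides had r across features between 0.27 and 0.48 with the floret slides as deposited, and between -0.05 and 0.05 with them turned by the dyes. Dye swaps of 1 set had r between 0.16 and 0.57 as deposited. The dye effect of the stage slides had r between 0.04 and 0.26 with the 12 floret slides whose upper pool was labelled with Cy5, and between -0.27 and -0.04 with the other 12. Slides that compare stages were read as Cy5 over Cy3. This last sign has no test of its own other than the meiosis genes, and turning it exchanges every higher and lower, between stages and between florets.

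Values were divided by the natural log of 2, each scan was centred on its median, and the 3 scans of a slide were averaged. Pool values per set were then fitted to the slides by least squares (MASS 7.3.60.0.1, R 4.3.3), relative to the mean of the set's 12 pools. A linear model with 12 groups of stage and floret and a term for set was fitted to the pool values with limma 3.58.1, which shares the variance across features, with 11 residual degrees of freedom per feature. A feature was called at a Benjamini-Hochberg adjusted p under 0.05, adjusted over all features. For neighbouring stages and for florets at each stage, p-values of all steps or stages were adjusted together within each question. The comparisons were the effect of stage in each floret (F test), the last against the first stage, the 5 steps between neighbouring stages, upper against lower florets at each stage and averaged over stages, and the interaction of floret and stage. Scans were compared by a permutation test of paired differences in spread (100000 sign flips, two-sided, Benjamini-Hochberg over 3 comparisons). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

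Features were linked to genes by the array annotation and the maize reference: 6412 features had 1 gene, 214 several and 5534 none, and 6358 were matched by gene number. Features with 1 gene stood for 4903 genes. Genes are named by a rule fixed before the data were examined, as were the comparisons, the first set of lists and the alternatives not said to be added. The rule takes the 10 with the largest change per direction among called features with a gene name and the same sign in both sets for the first-to-last changes and the floret average, 2 per direction for each step and stage, the 5 smallest p-values of each F test, and the 3 largest changes of each list that passed. What counts as a gene name was settled later, as a symbol or synonym that is not a locus, clone, marker or EST identifier, which 1143 features of 795 genes have. Other genes drawn from the lists, second features of a gene, and the 6 genes shown as profiles were chosen after their values were seen, as was the remark on the names of MADS5.

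Gene lists were matched by symbol and synonym and tested with camera (limma, preset correlation 0.01) where they had 5 or more features, with p-values adjusted over the tests of each set of lists, and again with the correlation estimated per list. Of the 20 lists of the first set, 7 were tested (pollen and pectin enzymes, photosynthesis, starch and sucrose, flavonoids, heat shock and chaperones, ubiquitin and proteasome, cytoskeleton). Another 5 had 1 to 4 features (meiosis, tapetum, lipid transfer proteins, jasmonate and oxidative stress, kernel storage proteins), and 8 had none. A further 14 lists were written after the feature names had been seen: DNA replication, histone genes, light harvesting, ribosomal proteins, jasmonate genes, cellulose synthases, aquaporins, glutathione transferases, antioxidant enzymes, folding in the endoplasmic reticulum, glycolysis, phenylpropanoid genes, MADS box genes, and cysteine proteases and cystatins. Tests of whether a list changed differently in upper and lower florets were added after the counts of the heat shock list had been seen. Several features of 1 gene are not independent, and camera counts each.

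The fit was tested on simulated data with the residual spread of the real pools. Unchanged pools gave 0 or 1 called features per comparison, and 4.5% of random lists had a camera p under 0.05. Features were simulated independently of each other, so the random lists held no genes that vary together. The share of 4.5% therefore cannot tell whether the preset correlation of camera holds for the real lists. Recovery was tested with 200 of 12160 features changed. Of features changed 1.5-fold, 2-fold and 4-fold, 13.4%, 38.8% and 80.3% were called from the first to the last stage in upper florets. For the floret average these shares were 61.2%, 92.5% and 100%. The agreement between the 2 pools of a stage and floret across features had r from 0.370 to 0.688, with a median of 0.553. Scans of 1 slide had median Spearman correlations of 0.739 (low and high), 0.752 (low and medium) and 0.790 (medium and high) across features. Of the 48 slides, 5 had a residual spread more than 1.5 times the median of 0.296 (0.473 to 0.577), and were kept. All of them were floret slides of set 1 that held meiocyte, dyad/tetrad or tetrad pools.

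The alternatives fixed in advance were each scan alone, the median of the scans, the smallest of their p-values times 3, no centring, scaling to 1 spread, robust variance, the slide as the replicate, no term for set, direct slides only, camera with an estimated correlation and each pool left out. The planned turning of floret slides by the dyes was also run. Those chosen after seeing the data were the 5 noisy slides left out and the most repeated value of each scan left out. Filters on missing values or identical scans changed nothing, as there were none, and were not run.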

Results

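Gene expression was measured in anthers of the maize inbred line Ky21 with spotted cDNA arrays read in 2 colours. Each spikelet of a maize tassel holds an upper and a lower floret, and anthers of both were staged by light microscopy as meiocyte, dyad/tetrad (mixed), tetrad, early microspore, mid-microspore or mid/late microspore (mixed). For each of the 6 stages and each floret there were 2 RNA pools, 24 in all, each made from 1 to 4 individuals with 8 to 20 anthers per tassel. The pools formed 2 sets of 12, and each of 48 slides held 2 pools of one set: 24 slides compared stages within a floret and 24 compared the florets at one stage. Every slide was scanned at low, medium and high intensity, which gave 3 scans of 12160 features per slide with no missing values. A pool's value is given on the log2 scale relative to the mean of the 12 pools of its set, so that ratios between pools, and no absolute levels, were measured. The base of the deposited logs was read from the values, and every log2 ratio and fold given depends on that reading. With 2 pools per stage and floret, the p-values measure the spread between these pools, not between plants.

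The labels name the dye of each pool but not the numerator of the deposited ratio. Ratios between stages were read as Cy5 over Cy3 because the listed meiosis genes then had a median log2 ratio of -1.04 in upper florets and -0.91 in lower florets from the first to the last stage. These medians rest on 4 features, of which 3 fell past the threshold in upper and 2 in lower florets. In lower florets 1 of them stood above 0. The pollen and pectin enzyme list, with medians of -0.33 and -0.08, did not pass and settles no sign. Every direction given is therefore at most likely, and is not stated by the labels. With the sign turned, each higher and lower exchanges, and the direction of the meiosis genes themselves is not independent evidence. One gene of the tapetum list, ms23, a transcription factor gene needed for normal tapetum development, had log2 ratios of 0.60 and 0.74 over the same interval.

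Which genes change over anther development in upper florets was the first question of the design. From meiocytes to mid/late microspores, ZmCASP1 (feature 11735) rose 60.8-fold in upper florets, with a log2 ratio of 5.93 ± 0.46 (SE, n = 2 pools per stage, adjusted p = 1.62e-06). The aldehyde dehydrogenase gene aldh5, also listed as rf2d (feature 8911), rose 21.6-fold (4.43 ± 0.45, adjusted p = 1.34e-05), and its other feature, 344, had a log2 ratio of 2.94. Among called features with a gene name, the largest fall was that of HSP18 (feature 10638), a small heat shock protein gene (-4.70 ± 0.56, adjusted p = 5.23e-05), followed by hsp18c (feature 10219), another small heat shock protein gene (-4.09 ± 0.35, adjusted p = 3.32e-06). In all, 3246 of 12160 features changed, 1610 higher and 1636 lower at the last stage, with a median 1.93-fold change among them (limma, Benjamini-Hochberg adjusted p under 0.05). Changes in the sets of pools had r = 0.663 across features. With the median of the 3 scans in place of their mean, ZmCASP1 had a log2 ratio of 4.81.

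The other 8 named genes that rose in upper florets had log2 ratios from 2.60 to 3.62. They were Amy2, also listed as the beta-amylase gene BMY1 (3.62 ± 0.64), GPRP (3.54 ± 0.39), the sucrose phosphate synthase gene SPS (3.08 ± 0.40), prp2 (3.07 ± 0.35), the potassium transporter gene HAK1 (2.92 ± 0.51), the protein kinase gene SnRK2.8 (2.89 ± 0.69), the glutathione transferase gene gst19 (2.77 ± 0.49) and bss1 (2.60 ± 0.31). The other 8 that fell had log2 ratios from -3.41 to -2.72. They were the glutathione transferase gene gst28 (-3.41 ± 0.45), AGP2 (-3.14 ± 0.65), the calreticulin gene CRH, also listed as CRT (-3.12 ± 0.50), the jasmonate response repressor gene JAZ9 (-2.91 ± 0.31), pdh2, which encodes the E1 beta subunit of pyruvate dehydrogenase (-2.84 ± 0.22), the small heat shock protein gene hsp22 (-2.73 ± 0.66), the protein phosphatase gene PP2C24 (-2.73 ± 0.26) and rf2 (-2.72 ± 0.51). Features of one gene did not always go together: feature 2063 of gst28 rose (1.39), as did feature 6042 of rf2 (0.83), while features 4999 and 5131 of rf2 fell (-1.35 and -0.71). Feature 8886 of hsp22 did not pass (-0.36, adjusted p = 0.584). Several of these calls were less firm: SnRK2.8 had an adjusted p of 0.113 with the low scan alone and 0.103 when columns were scaled to one spread, and CRH of 0.334 and 0.0555 with the low and the medium scan and 0.0607 from the smallest of the 3 scans' p-values. Without the upper meiocyte pool of set 1, AGP2 and hsp22 missed the threshold, with log2 ratios of -2.09 and -2.41. The sets of pools gave AGP2 -4.35 and -1.93, so the size of its fall rests in part on that pool. With the median of the 3 scans, folds shrank by more than 1.5 times for SPS (2.06), HAK1 (2.34), SnRK2.8 (1.95), gst19 (2.14), gst28 (-2.19), AGP2 (-1.82) and rf2 (-1.62). Without the upper mid/late microspore pool of set 2 hsp22 missed the threshold (-2.44), and without that of set 1 SnRK2.8 did (2.69).

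Heat shock and chaperone genes fell as a group in upper florets: 17 of 24 features, which stand for 10 genes, were lower at the last stage, and 20 were when adjusted over the list alone. The list's median log2 ratio was -0.86 (camera, adjusted p = 5.40e-08, but adjusted p = 0.350 with an estimated correlation). By set of pools the median was -1.29 in set 1 and -0.57 in set 2, and the upper mid/late microspore pool of set 1 stood lowest, so the size of the fall rests in part on that pool. Of the small heat shock protein genes, HSP18, hsp18c, feature 4183 of hsp22 and feature 5649 (-0.71) fell, while both features of hsp18f (adjusted p = 0.493 and 0.102), feature 6747 (-0.05), of the same gene as 5649, and feature 8886 of hsp22 did not pass. The gene hsp101 and the features of HSP90-1 (-1.43 and -1.30) and HSP90-2 (-1.29 and -1.16) fell. Of 23 photosynthesis features, 10 rose and 4 fell, or 11 and 4 when adjusted over the list alone (adjusted p = 0.0406, and adjusted p = 0.396 with an estimated correlation). The Rubisco small subunit gene rbcS had features at 2.58 and 1.83, and psaH had a feature at 1.66. One feature of the chlorophyll-binding protein gene cab-m1 fell (-1.79), as did the malic enzyme gene me3 (-0.61 and -0.50) and psat1 (-0.83), which are not photosystem genes. Of 32 cytoskeleton features, 8 rose and 1 fell, or 9 and 1 when adjusted over the list alone, with the tubulin genes tua6 (1.18) and tub3 (1.05 and 0.93) highest and the gamma-tubulin gene TUBG3 the one that fell (-0.74). This list had an adjusted p = 5.46e-04, and adjusted p = 0.350 with an estimated correlation. Of 7 ubiquitin features, 5 of the gene MUB14 rose (highest 1.05, 0.94 and 0.91), or 6 rose and 1 of MUB6 fell when adjusted over the list alone (adjusted p = 0.00368, and adjusted p = 0.350 with an estimated correlation). With the high scan alone the heat shock list passed, and photosynthesis (adjusted p = 0.0526), cytoskeleton (0.118) and ubiquitin (0.248) did not. Photosynthesis also missed the threshold with the medium scan alone (0.0577).

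Starch and sucrose, flavonoid and pollen lists did not pass in upper florets. Of 11 starch and sucrose features, 2 rose and 3 fell, or 5 and 3 when adjusted over the list alone (adjusted p = 0.716), among them one feature of the sucrose synthase gene ss2, also listed as sus1 (2.41), and the starch branching enzyme gene ae1 (-0.71). Of 6 flavonoid features, 3 rose, all of the chalcone synthase gene c2 (1.46, 1.41 and 1.21), and 3 did when adjusted over the list alone (adjusted p = 0.0830). Of 7 pollen and pectin enzyme features, 3 rose, 2 of profilin-2 (0.75 and 0.55) and 1 of the polygalacturonase gene PG14 (1.80), and 3 did when adjusted over the list alone (adjusted p = 0.716). Profilin-2 is a synonym of PRO4, which was matched by that name and need not be a pollen gene. The median of the pollen list was -0.33 while its mean was 0.14 and the test pointed up. Lists with fewer than 5 features were not tested as groups. Of 4 meiosis features, ZYP1, which encodes a protein of the synaptonemal complex (-2.02), the recombinase gene rad51a (-1.36) and the cohesin gene afd1 (-0.72) fell, 3 as well when adjusted over the list alone. Of 4 lipid transfer protein features, 3 of LTP3 rose (0.84 to 2.14), and 4 did when adjusted over the list alone. Of 4 tapetum features, 0 passed by limma and 0 when adjusted over the list alone, and 1, ms23, had an unadjusted p under 0.05. Catalase genes went both ways: catalase1 rose (1.33) and CAT3 fell (-1.26), which are both features of the jasmonate and oxidative stress list, 1 and 1 also when adjusted over the list alone. Of 2 features for storage proteins of the kernel, a tissue not sampled here, 0 passed by limma, and GLB1 (1.82) did when adjusted over the list alone, being also the 1 with an unadjusted p under 0.05.

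**Figure D1:**
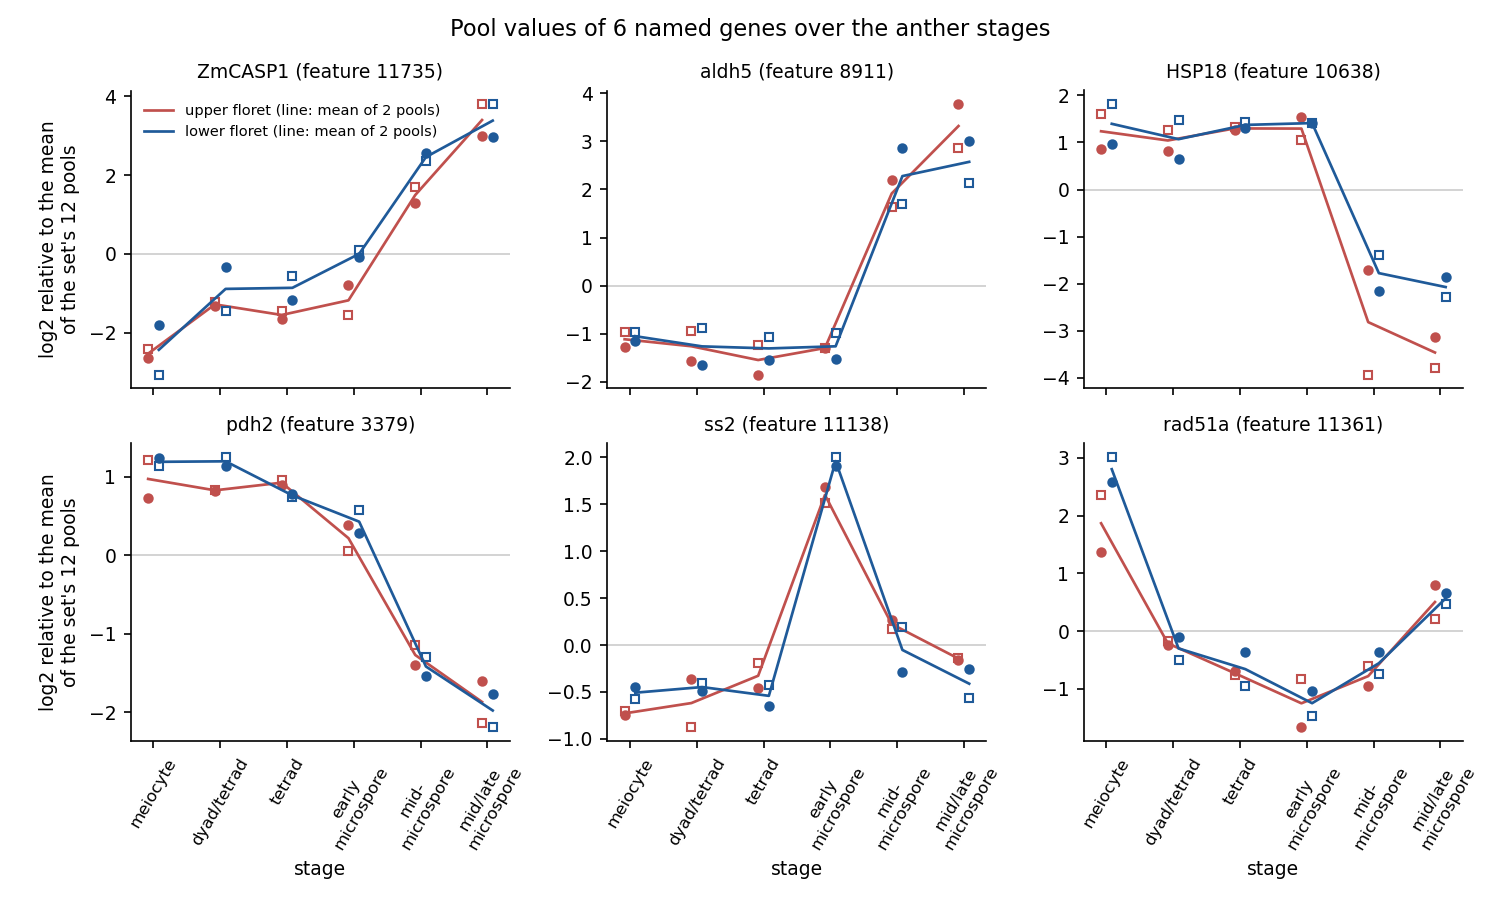
Values of 6 named genes in the 24 pools over the 6 stages (log2 relative to the mean of the 12 pools of the set). Filled circles are set 1, open squares set 2, and lines join the means of 2 pools for upper (red) and lower (blue) florets; ZmCASP1 and aldh5 were highest and HSP18 and pdh2 lowest in mid/late microspores, ss2 was highest in early microspores, and rad51a was highest in meiocytes.

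The same question was asked for lower florets. There ZmCASP1 (5.81 ± 0.46, adjusted p = 1.95e-06) and aldh5 (3.62 ± 0.45, adjusted p = 6.69e-05) again showed the largest rises among called features with a gene name, 56.3-fold and 12.3-fold from meiocytes to mid/late microspores. The median of the 3 scans gave ZmCASP1 a log2 ratio of 4.91. Of the named genes HSP18 had the largest fall (-3.47 ± 0.56, adjusted p = 5.50e-04), and pdh2 fell by 8.97-fold (-3.17 ± 0.22, adjusted p = 1.06e-06). In all, 3379 of 12160 features changed, 1733 higher and 1646 lower at the last stage, with a median 1.93-fold change among them, and the sets had r = 0.709 across features. Features higher at the last stage in both florets numbered 1222, where lists of these lengths drawn independently would share 229, and features lower in both numbered 1207 (221 for independent lists). In opposite directions there were 0 and 1 (limma). Across features, the changes in upper and lower florets had r = 0.879 and a covariance of 0.566. Pools of one set share slides, and simulated unchanged pools gave r = 0.235 and a covariance of 0.0286.

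Of the 10 named genes per direction, 8 that rose and 7 that fell were named in both florets. Amy2 (3.38), gst19 (3.04), SPS (2.92), prp2 (2.80), GPRP (2.72) and SnRK2.8 (2.65) were the other shared genes that rose in lower florets, together with rbcS (2.96 ± 0.32) and dxr, which encodes an enzyme of plastid isoprenoid synthesis (2.78 ± 0.46). The other shared genes that fell were gst28 (-3.20), rf2 (-3.06), AGP2 (-2.99), CRH (-2.76) and JAZ9 (-2.57). Named in lower florets alone were cyclin4 (-3.01 ± 0.24), ec2e, also listed as the ribosomal protein gene rpl39 (-2.64 ± 0.28), and the spindle checkpoint gene mad2 (-2.61 ± 0.36). With the median of the 3 scans, folds shrank by more than 1.5 times for gst19 (1.99), SPS (2.07), dxr (1.93), SnRK2.8 (1.49), gst28 (-2.10), rf2 (-2.02), cyclin4 (-2.35), AGP2 (-1.46), ec2e (-1.58) and mad2 (-1.56). Feature 2063 of gst28 and feature 6042 of rf2 (0.86) again rose, and feature 2086 of ec2e stood at 0.10. SnRK2.8 had an adjusted p of 0.0720 with the low scan alone, 0.0791 with the medium scan and 0.179 with columns scaled to one spread. That of CRH was 0.399 with the low scan, 0.0799 with the medium scan and 0.113 from the smallest of the 3 scans' p-values, and that of prp2 was 0.0636 with the high scan. SnRK2.8 also missed the threshold without the lower mid/late microspore pool of set 1 (adjusted p = 0.135) or the lower meiocyte pool of set 2 (0.0795), and AGP2 without the lower meiocyte pool of set 1 (0.0671).

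In lower florets, 4 of 24 heat shock and chaperone features fell, and 4 when adjusted over the list alone: the 2 features of HSP18 (-3.47 and -3.07), hsp18c (-1.22) and hsp101 (-0.95). The list median was -0.36 (adjusted p = 0.00788, and adjusted p = 0.475 with an estimated correlation). Of 23 photosynthesis features, 11 rose and 2 fell, or 12 and 3 when adjusted over the list alone (adjusted p = 0.00788, and adjusted p = 0.350 with an estimated correlation), with features of rbcS (2.96 and 1.84) and psaH (2.01) highest and 1 of cab-m1 (-1.73) lowest. Of 32 cytoskeleton features, 9 rose and 2 fell, or 16 and 2 when adjusted over the list alone, again with tua6 (1.11) and tub3 (0.94 and 0.90) highest and both falls in TUBG3 (-0.92 and -0.65; adjusted p = 7.33e-04, and adjusted p = 0.350 with an estimated correlation). Of 7 ubiquitin features, 6 of MUB14 rose (highest 1.03, 0.88 and 0.87) and 1 of MUB6 fell (-0.85), as they did when adjusted over the list alone (adjusted p = 0.00516, and adjusted p = 0.350 with an estimated correlation). Of 7 pollen and pectin enzyme features, 2 of profilin-2 rose, or 2 rose and 1 of PRO1 fell when adjusted over the list alone (adjusted p = 0.716). Of 11 starch and sucrose features, 2 rose and 2 fell, as they did when adjusted over the list alone (adjusted p = 0.876). Of 6 flavonoid features, 2 of c2 rose, or 2 rose and 1 of A1 fell when adjusted over the list alone (adjusted p = 0.708). The pollen list had a median of -0.08 and a mean of 0.12, and the starch list a median of 0.10 and a mean of -0.01, and both tests pointed up. Among lists with fewer than 5 features, rad51a (-2.24) and afd1 (-0.74) fell of the 4 meiosis features, and all 4 lipid transfer protein features rose (LTP3 at 0.75 to 1.44 and plt2 at 0.67). With the median of the 3 scans rad51a had -1.27. The gene ms23 rose (0.74) of the 4 tapetum features, catalase1 rose (1.25), and bz15, a zein gene also listed as zp15, rose (1.38). Counts adjusted over the list alone were 2, 4, 1 and 1 for these lists, and 2 for the kernel storage proteins. With the high scan alone, the heat shock (adjusted p = 0.0526), cytoskeleton (0.0820) and ubiquitin (0.262) lists did not pass in lower florets.

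**Figure D2:**
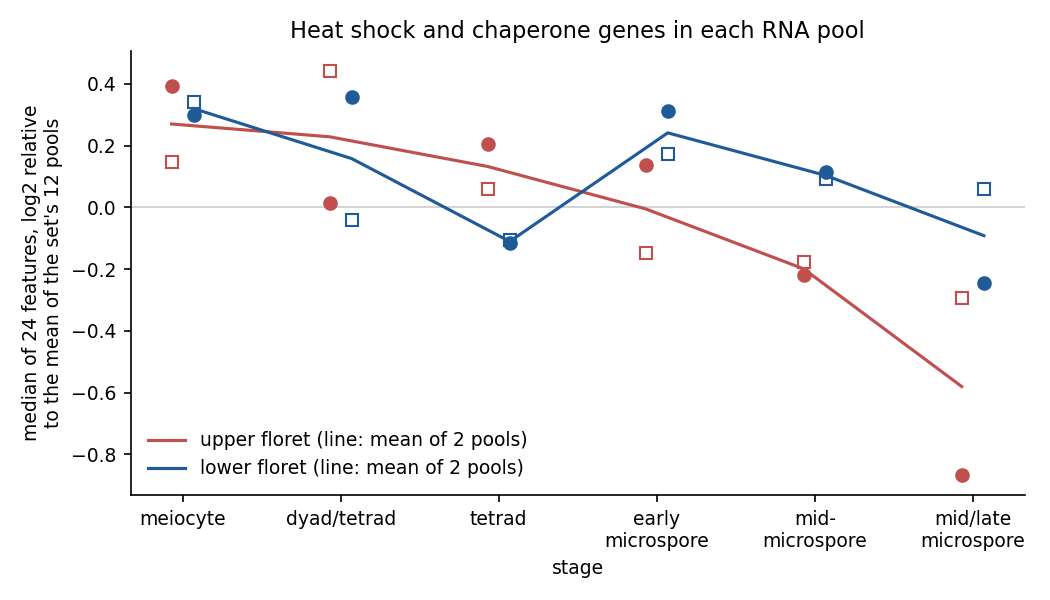
Median of the 24 heat shock and chaperone features in each of the 24 pools over the 6 stages (circles set 1, squares set 2; lines join the means of 2 pools for upper, red, and lower, blue, florets). At the mid/late microspore stage the medians were -0.87 and -0.29 in the upper pools and -0.24 and 0.06 in the lower pools.

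Each first-to-last count rests in part on single pools. The count in upper florets was 1770 without the meiocyte pool of set 1 and 2079 without the mid/late microspore pool of set 1, and 1376 with columns scaled to one spread. In lower florets it was 2016 and 2017 without the mid/late microspore pool of set 2 or of set 1, 2139 without the meiocyte pool of set 1, and 1507 with columns scaled to one spread.

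Over all 6 stages, 4562 features in upper florets and 4566 in lower florets varied (limma F tests). Among features with a gene name, the smallest p-values belonged to aldh5 (feature 344) in both florets, whose pool means in upper florets lay between -0.87 and -0.59 up to early microspores and then reached 1.24 in mid-microspores and 2.14 in mid/late microspores. Next in upper florets were pdh2, ZmCASP1, PP2C18 and PP2C24, and in lower florets pdh2, cyclin4, ss2 and the gene ltk1. The adjusted p-values of these genes were 4.97e-06 or less in upper florets and 4.37e-06 or less in lower florets. The sucrose synthase gene ss2 (feature 11138) stood highest in early microspores, at 1.60 in upper and 1.96 in lower florets, and lay between -0.73 and -0.33 at the earlier stages.

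Most changes between neighbouring stages fell on 2 steps, tetrad to early microspore and early to mid-microspore. Into early microspores the mitochondrial porin gene vdac2 rose in both florets (2.40 ± 0.34 in upper and 3.23 ± 0.34 in lower florets), as did ACR4 in upper florets (2.49 ± 0.41) and ss2 in lower florets (2.50 ± 0.20). JAZ9 fell at the same step (-1.72 ± 0.31 and -1.38 ± 0.31), as did PP2C24 (-1.59 ± 0.26 and -1.38 ± 0.26). From early to mid-microspores aldh5 rose (3.21 ± 0.45 in upper and 3.54 ± 0.45 in lower florets), with ZmCASP1 in upper (2.67 ± 0.46) and SPS in lower florets (2.84 ± 0.40). The gene sbp27 fell in both florets (-3.90 ± 0.46 and -3.75 ± 0.46), with HSP18 in upper (-4.11 ± 0.56) and vdac2 in lower florets (-3.40 ± 0.34). With single pools left out, the log2 ratio of HSP18 at this step ran from -5.32 to -2.89. By the median of the 3 scans, sbp27 had -2.42 and -2.70, and SPS in lower florets 1.79. In upper florets 465 features changed into early microspores (236 higher) and 655 from early to mid-microspores (256 higher). In lower florets these counts were 492 (248 higher) and 927 (381 higher). The falls from early to mid-microspores shared 318 features between florets, against 17.9 for independent lists.

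The steps before the tetrad stage changed fewer features: 55 in upper and 27 in lower florets from meiocytes to dyads/tetrads, then 17 and 98 to tetrads. The recombinase gene rad51a fell from meiocytes to dyads/tetrads in both florets (-2.08 ± 0.35, adjusted p = 0.00707, and -3.10 ± 0.35, adjusted p = 3.43e-04), and afd1 fell in upper florets (-1.35 ± 0.19, adjusted p = 0.00227). With the medium scan alone none of these 3 calls stayed (adjusted p = 0.228 and 0.195 for rad51a and 0.0627 for afd1), and rad51a in upper florets also missed with the low (0.344) and the high scan (0.0639). With the median of the 3 scans, rad51a had log2 ratios of -1.67 and -1.69, so that its larger fall in lower florets was not seen, and ec2e had -1.02. At this step CPK39 rose in upper (1.81 ± 0.44) and OBF1 in lower florets (1.66 ± 0.40), and ec2e fell in lower florets (-1.62 ± 0.28). With single pools left out, CPK39 ran from 0.97 to 2.65 and OBF1 from 0.80 to 2.52. To tetrads the autophagy gene Atg8d rose (0.80 ± 0.18) and DBP2 (-1.18 ± 0.23) and PP2C18 (-0.87 ± 0.21) fell in upper florets. In lower florets sbp27 (2.32 ± 0.46) and the aquaporin gene tip1 (2.17 ± 0.41) rose and CAT3 (-1.05 ± 0.26) and TIFY23 (-0.96 ± 0.23) fell. From mid- to mid/late microspores 70 features rose and 74 fell in upper florets. There ZmCASP1 (1.90 ± 0.46) and the aldehyde dehydrogenase gene aldh2 (1.75 ± 0.31) rose and 4CL (feature 10142, -1.79 ± 0.43), a gene of phenylpropanoid synthesis, and hsp18c (-1.58 ± 0.35) fell. In lower florets 89 changed at this step, with bss1 (1.53 ± 0.31) and ltk1 (1.42 ± 0.16) rising and the enolase gene feature 1861 (-1.23 ± 0.29) and GPDH4 (-0.89 ± 0.21) falling. With the median of the 3 scans, Atg8d (adjusted p = 0.702), DBP2 (0.140), aldh2 (0.161), OBF1 (0.580), CAT3 (0.101) and TIFY23 (0.453) did not pass at these steps. Between the sets of pools, changes correlated across features with r of -9.20e-04 and -0.112 for the first step in upper and lower florets, 0.110 and 0.0658 for the next, 0.574 and 0.595 into early microspores, 0.586 and 0.661 to mid-microspores, and 0.330 and 0.197 for the last step.

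At the steps into early and mid-microspores, 14, 16 and 16 of 16 named calls stayed with the low, medium and high scan alone. With the low scan ZmCASP1 in upper florets (adjusted p = 0.151) and JAZ9 in lower florets (0.106) did not. JAZ9 in lower florets also missed the threshold from the smallest of the 3 scans' p-values (0.0673) and without the 5 noisy slides, those of large residual spread (0.0608). From the slides that compared the 2 stages directly, 11 of the 16 passed, and JAZ9 (0.114 and 0.185), PP2C24 (0.0913 and 0.171) and sbp27 in lower florets (0.0901) did not. Of 24 pools left out in turn, 3 ended the call of JAZ9 in upper and 4 in lower florets, 2 that of PP2C24 in each floret, 2 that of ZmCASP1 and 1 that of ACR4, the early microspore pool of set 1.

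At the other 3 steps the named calls were less firm: of 21, 7 stayed with the low scan alone, 5 with the medium, 8 with the high, 6 from the smallest of the 3 scans' p-values and 3 from direct slides. Those 3 were afd1, rad51a in lower florets and ltk1, while rad51a in upper florets missed the threshold there (adjusted p = 0.0890) and from the smallest p-values (0.124). No single scan kept CPK39 (0.105, 0.0713 and 0.0541 with the low, medium and high scan), OBF1 (0.511, 0.715 and 0.275), ec2e (0.0700, 0.218 and 0.351), DBP2 (0.0612, 0.346 and 0.676), PP2C18 (0.0686, 0.250 and 0.190), CAT3 (0.232, 0.433 and 0.251), TIFY23 (0.438, 0.502 and 0.838), aldh2 (0.270, 0.157 and 0.609) or 4CL (0.0584, 0.0529 and 0.0750). Atg8d (0.735 and 0.752) and ZmCASP1 (0.506 and 0.0716) missed with the low and the medium scan, and sbp27 (0.0762) and tip1 (0.0757) with the low scan. With the medium and the high scan bss1 (0.0562 and 0.0623) and enolase (0.0566 and 0.195) missed, and with the high scan hsp18c (0.0540). Scaled columns ended 5 of the 21 calls, those of CPK39, ZmCASP1, 4CL, hsp18c and enolase, and robust variance those of CPK39 and CAT3. Without the noisy slides 12 stayed, and CPK39, PP2C18, hsp18c, OBF1, ec2e, sbp27, CAT3, TIFY23 and enolase did not. With the most repeated values left out 14 of the 19 that could be tested stayed, and CPK39, PP2C18, ZmCASP1, OBF1 and CAT3 did not. Of 24 pools left out in turn, 22 ended the call of enolase, 21 those of CPK39 and CAT3, 19 those of 4CL and OBF1, 18 that of ZmCASP1, 16 that of PP2C18, 15 that of TIFY23, 8 that of Atg8d and 7 that of GPDH4. Fewer did for hsp18c (4), DBP2 and sbp27 (3 each), tip1, aldh2 and bss1 (2 each) and rad51a in upper florets (1, the meiocyte pool of set 2).

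**Figure D3:**
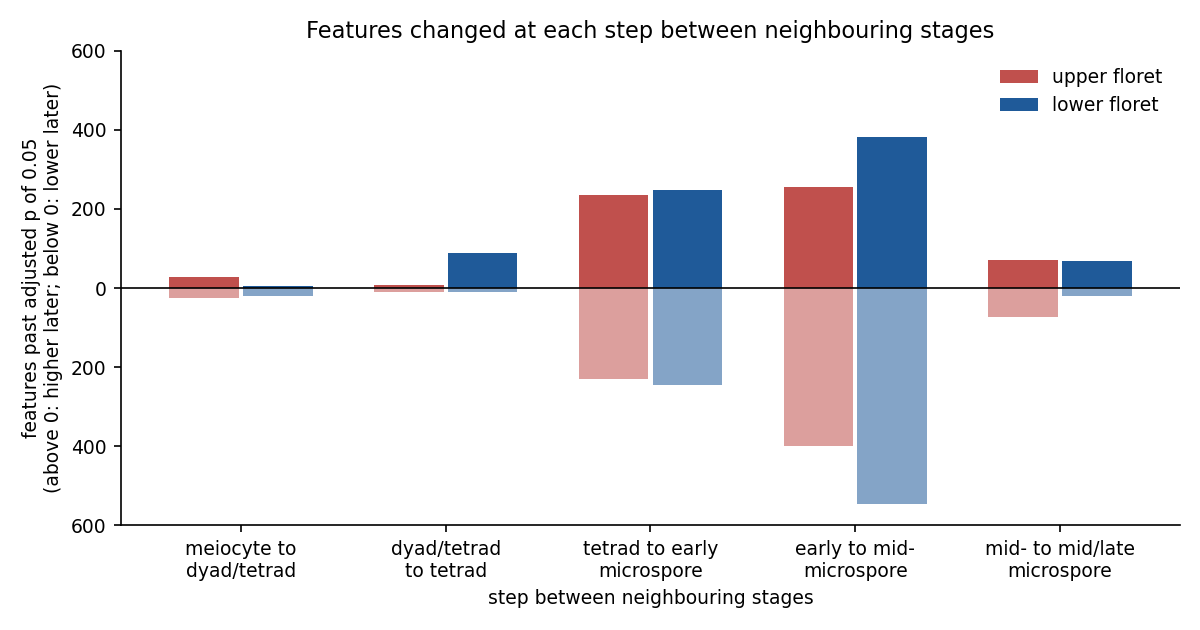
Features past an adjusted p of 0.05 at each of the 5 steps between neighbouring stages, those higher later above 0 and those lower later below 0, for upper (red) and lower (blue) florets. The steps into early and into mid-microspores had 465 and 655 features in upper florets and 492 and 927 in lower florets.

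Counted once each, 1151 features changed at 1 or more steps in upper florets and 1386 in lower florets. Without single pools the upper count ranged down to 346 (early microspore pool of set 1), with 535 (early microspore, set 2), 584 and 668 (mid-microspore, sets 2 and 1) and 615 and 707 (tetrad, sets 1 and 2). The lower count ranged down to 478 and 527 (early microspore, sets 1 and 2) and 643 (mid-microspore, set 1). From the slides that compared the 2 stages directly, 314 and 394 features passed.

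The last question was how upper and lower florets differ at each stage. Averaged over the 6 stages, argonaute1 (feature 1965) was 4.09-fold higher in upper florets (2.03 ± 0.30, n = 12 pools per floret, adjusted p = 5.05e-04), and the lipoxygenase gene lox2 2.73-fold higher (1.45 ± 0.26, adjusted p = 0.00173). The gene MADS5, also listed as zmm8 and zmm14, names of MADS box genes known for expression in the upper floret, was higher there too (1.19 ± 0.12, adjusted p = 4.29e-05). The transcription factor gene bZip37 was 3.76-fold lower in upper florets by feature 8977 (-1.91 ± 0.17, adjusted p = 2.54e-05), while its other 3 features lay between -0.21 and -0.05 and did not pass. In all, 3252 features differed, 1680 higher and 1572 lower in upper florets, and the median fold among them was 1.28. The floret averages of the sets had r = 0.619 across features. These values rest on reading the floret slides as upper over lower floret, a choice made from the values. That reading depends on the sign of the stage slides, and with that sign turned, higher and lower in upper florets exchange. With the floret slides turned by the dyes, as first planned, 1 feature passed.

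Other genes higher in upper florets were the alcohol dehydrogenase gene adh1 (1.22 ± 0.18), the cellulose synthase gene cesa10 (1.10 ± 0.14), 4CL (feature 720, 1.04 ± 0.34), the protein kinase gene mpk6 (0.83 ± 0.08), the response regulator gene crr5 (0.80 ± 0.14), SRA (0.79 ± 0.19) and the catalase gene CAT3 (0.78 ± 0.11). Genes lower in upper florets were ec2e (feature 2086, -1.47 ± 0.20), hsp22 (feature 8886, -1.09 ± 0.18), PMP3 (-0.98 ± 0.15), the expansin gene expa2 (-0.88 ± 0.10), the beta-glucosidase gene glu1 (-0.85 ± 0.23), the histone gene his1a (feature 10084, -0.83 ± 0.11), the cystatin gene cc7 (-0.83 ± 0.09), TIFY2 (-0.81 ± 0.18) and the lactate dehydrogenase gene LDH (-0.76 ± 0.21). All 3 features of PMP3 and both of hsp22 were lower in upper florets. For ec2e, expa2 and crr5 the other features (8591 at 0.21, 1261 at 0.14, 7208 at -0.03 and 12112 at 0.07) did not pass, nor did feature 9138 of mpk6 (0.09) and feature 10814 of LDH (-0.06). Of the 7 other features of his1a, 6 did not pass, at -0.32 to 0.05, and feature 1264 did (-0.27, adjusted p = 0.0462). Feature 10163 of lox2 (1.19), 10415 of adh1 (0.28) and 2062 of 4CL (0.42) passed, and 4681 of lox2 (0.43) and 10142 of 4CL (0.48) did not. The call of LDH ended with the low scan alone (-0.01), the high scan alone (-0.52, adjusted p = 0.363), the median of the scans (-0.46, adjusted p = 0.172) or with the most repeated values left out (adjusted p = 0.0685). That of his1a ended with the high scan alone (-0.04, adjusted p = 0.454), and those of 4CL (0.145), SRA (0.141) and crr5 (0.0808) with the low scan alone. SRA also missed it from the slides of the compared pools alone (0.0598), and 4CL without any of 14 single pools, with adjusted p-values from 0.0551 to 0.0816.

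**Figure D4:**
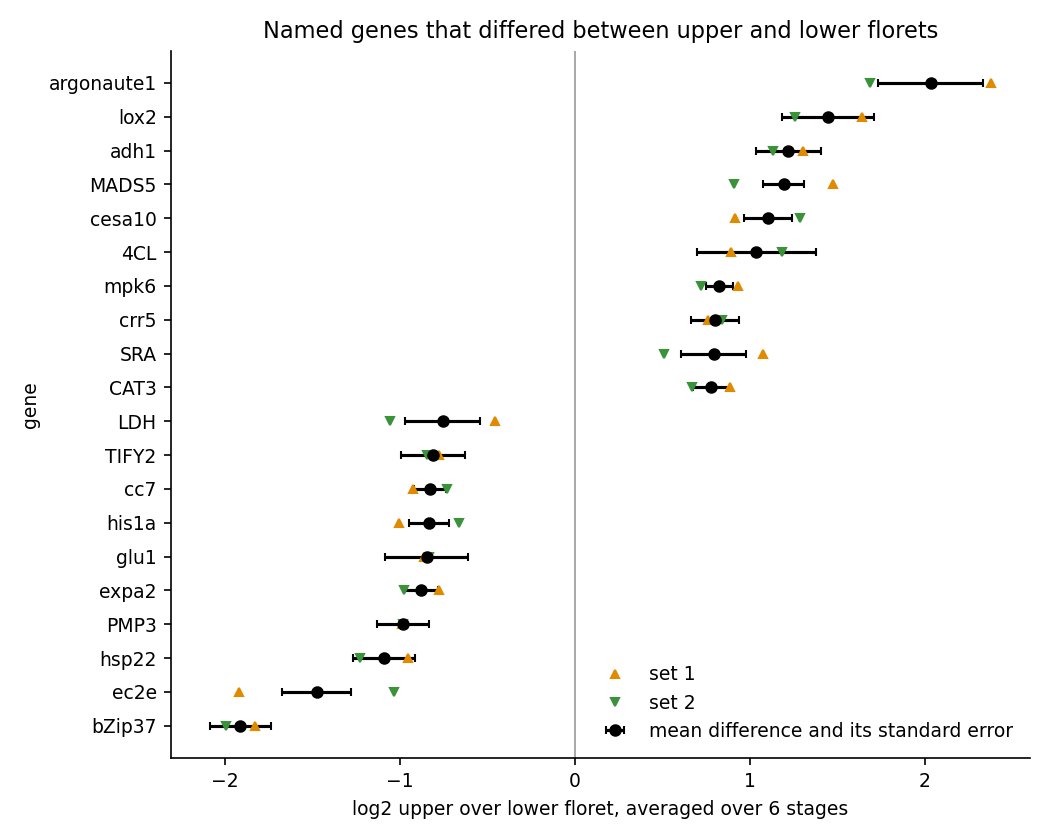
Log2 ratio of upper over lower florets, averaged over the 6 stages, for the 20 named genes (black circles with the standard error, 12 pools per floret), with the average of each set as triangles. Averages run from -1.91 for bZip37 to 2.03 for argonaute1, and both sets lie on the same side of 0 for every gene shown.

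Heat shock and chaperone genes were lower in upper florets on average, 5 of 24 features when adjusted over all features and 5 when adjusted over the list alone, with 2 features of hsp22 and 1 each of hsp18c (-0.54), HSP90-2 (-0.40) and hsp70-4 (-0.27). The list test gave an adjusted p = 0.00788, and adjusted p = 0.475 with an estimated correlation. The average was not shared by all stages. List medians of the tetrad pools were higher in upper (0.21 and 0.06) than in lower florets (-0.11 and -0.11). From early microspores on, the upper pool was lower in each set, with -0.22 and -0.18 against 0.11 and 0.09 in mid-microspores. The average therefore overlaps the late fall in upper florets. Of 23 photosynthesis features, 8 were lower and 2 higher in upper florets, as they were when adjusted over the list alone (adjusted p = 0.0233, and adjusted p = 0.350 with an estimated correlation), with features of rbcS (-0.63), CAB1 (-0.53) and psbs1 (-0.44) among the lower ones and cab-m1 (0.46) highest. Of 32 cytoskeleton features, 7 were higher and 2 lower, or 9 and 2 when adjusted over the list alone (adjusted p = 0.0226, and adjusted p = 0.475 with an estimated correlation), with TUBG3 (0.48), tua3 (0.35) and Actin-7 (0.30) highest. Of 7 pollen and pectin enzyme features, the 2 of profilin-2 were lower, 2 also when adjusted over the list alone (adjusted p = 0.108). Of 11 starch and sucrose features, 1 was higher and 2 were lower, as when adjusted over the list alone (adjusted p = 0.708). The higher one was Agpat4 (0.42), which was matched by its symbol and need not be a starch or sucrose gene. The lower ones were GBSSIIa (-0.26) and Agp2 (-0.36). Of 7 ubiquitin features, 1 of MUB14 was higher, 1 also when adjusted over the list alone (adjusted p = 0.716), and the list had a median of -0.01, a mean of 0.04 and a test that pointed up. Of 6 flavonoid features, 0 passed by limma, 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05 (adjusted p = 0.737). Among the short lists, ms23 (0.37) and 1 metallothionein-like feature matched to the tapetum list by its symbol mtl1 alone (0.50) were higher in upper florets, and 2 were when adjusted over the list alone. CAT3 was the 1 feature of its list that passed, 1 also when adjusted over the list alone, and by limma 0 features of the meiosis, lipid transfer and kernel storage lists passed, 0 when adjusted over the list alone. At an unadjusted p under 0.05 these 3 lists had 0, 3 and 0 features. With the high scan alone, the heat shock, photosynthesis and cytoskeleton lists missed the threshold (adjusted p = 0.0526 for each).

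At single stages of development 17 features differed between florets, where a feature called at more than 1 stage is counted once. By stage the counts were 1 in meiocytes, 2 each in dyads/tetrads and tetrads, 5 in early microspores, 6 in mid-microspores and 4 in mid/late microspores. Of these, 2 carried a gene name: cyp10 was higher in upper florets in mid-microspores (0.93 ± 0.14, n = 2 pools per floret, adjusted p = 0.0453), and hsp18c was lower in upper florets in mid/late microspores (-2.55 ± 0.35, adjusted p = 0.0428). Of 24 pools left out in turn, 21 ended the call of cyp10 and 18 that of hsp18c. That of hsp18c also ended with the medium scan alone (adjusted p = 0.0546) and without the noisy slides (0.0532), and that of cyp10 from the slides of the compared pools alone (0.0877). With the floret slides turned by the dyes neither passed. The count was unstable, from 0 to 55 without single pools and 84 with the median of the 3 scans. Whether the floret difference varies with stage was tested by the interaction of floret and stage, which passed for 0 features by limma's F test, where 270 had an unadjusted p under 0.05. With no effect, a share of 0.05 of the 12160 features would be there, so 270 is low for this test. Pools that share slides were fitted as independent values. The 0 calls therefore do not show that the floret difference stays the same over the stages. The named genes with the smallest p were hsp18c (adjusted p = 0.697), VTE5, EF1-A, MAPK and CDPK1 (adjusted p = 1.00 for each).

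The scans of a slide are repeat readings of one hybridisation, and a stated aim was to gain power from scans of different intensity. The spread of log2 ratios over features was 0.946 ± 0.195 in low scans (SD over 48 slides), 0.864 ± 0.181 in medium scans and 0.787 ± 0.166 in high scans. Low scans were wider than high scans on 44 of 48 slides (mean difference 0.160, adjusted p = 1.50e-05, permutation test with 100000 sign flips, two-sided), medium wider than high on 39 (0.0778, adjusted p = 1.50e-05) and low wider than medium on 34 (0.0819, adjusted p = 0.006). The median absolute deviation, which is less open to extreme values, had means of 0.434, 0.437 and 0.389 in low, medium and high scans, so that low scans were not wider than medium scans by that measure, and it was not tested. The tests of low against high and medium against high had the smallest p that the permutations can give, 1.00e-05. The residual spread of pool values had medians of 0.278, 0.228 and 0.210 with the low, medium and high scan, 0.237 with the mean of the 3 scans and 0.212 with their median. First-to-last calls in upper florets numbered 2962, 2972 and 2763 with the low, medium and high scan alone, 3246 with the mean and 3451 with the median. For the floret average they numbered 2617, 3130, 3107, 3252 and 3659 in the same order, and at single stages 33, 14, 18, 17 and 84. A share of each low scan held one repeated value, at 185 to 2285 features, against 13 to 421 in high scans.

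**Figure D5:**
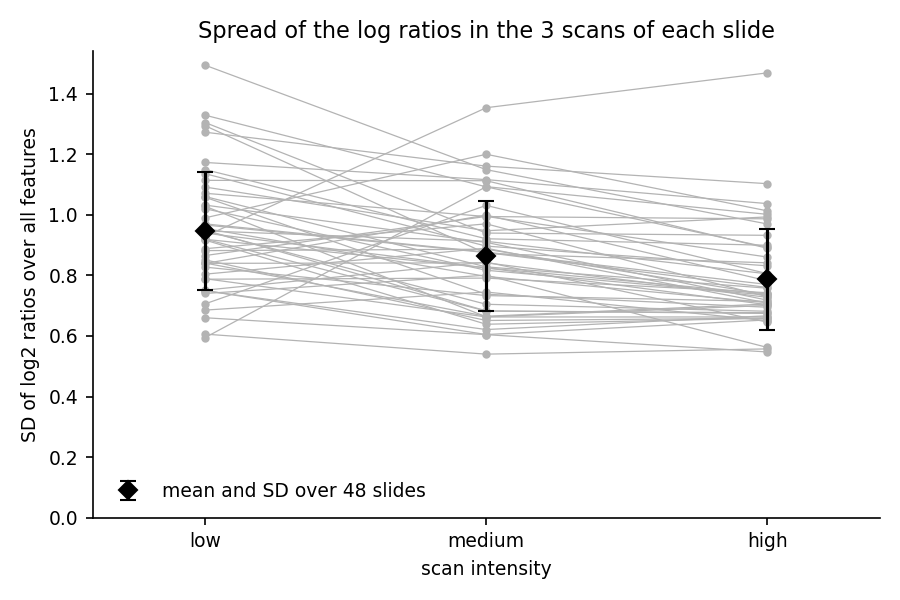
Standard deviation of the log2 ratios over 12160 features in the low, medium and high scan of each of 48 slides (grey lines join the scans of a slide; diamonds are the mean and SD over slides). The means were 0.946, 0.864 and 0.787.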

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

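The tests of whether a list's change from the first to the last stage differed between upper and lower florets were chosen after the counts of the heat shock list had been seen, and so was the test on single sets of pools. Of 21 lists tested, 4 differed with a preset correlation and are given here for that reason; 0 did by camera with an estimated correlation. Single features gave 0 calls of this difference by limma, with 269 at an unadjusted p under 0.05. That is less than the share of 0.05 of 12160 features that no effect would give, so the 0 calls do not show equal changes.

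Heat shock and chaperone genes fell further in upper than in lower florets, with a median difference of -0.43 over 24 features (adjusted p = 3.99e-12, and adjusted p = 0.133 with an estimated correlation). Cellulose synthase genes rose less in upper florets (median difference -0.37 over 11 features, adjusted p = 0.00297, and adjusted p = 0.720 with an estimated correlation). Flavonoid genes had a median difference of 0.48 over 6 features, of which 3 belong to c2 (adjusted p = 0.0298, and adjusted p = 0.449 with an estimated correlation). Histone genes had a median difference of 0.12 over 22 features (adjusted p = 0.0178, and adjusted p = 0.720 with an estimated correlation). In each list both sets of pools had the same sign: -0.70 and -0.23 for heat shock, -0.27 and -0.35 for cellulose synthases, 0.66 and 0.26 for flavonoids, and 0.20 and 0.12 for histones. With single scans, the heat shock list passed with each, the cellulose synthases missed the threshold with the high scan (adjusted p = 0.0680), and the flavonoids with the medium (0.163) and the high scan (0.0624).

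For the heat shock list, a shift of upper pools to a later point of the stage series at the last stage would move all features with their own stage change. The difference between florets was unrelated to the mean change across features (r = 0.0135). This r reflects only whether the changes spread equally widely in the 2 florets. It could miss a shift that follows the last step more than the whole series, so it does not decide the question. Whether 1 set of pools carries the difference stays open: the medians were -0.70 in set 1 and -0.23 in set 2, with spreads of 0.34 and 0.11 between genes, and only set 1 lay beyond a bound of -0.2 by more than its spread, a condition added after these medians were seen. Warmth or handling of single plants may have acted on these genes, and the upper mid/late microspore pool of set 1 had the lowest list median of all pools (-0.87); no label records either. A biological difference between upper and lower florets remains possible and was not tested apart from these.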

How the results depend on the processing

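With the floret slides as deposited, no named result changed sign: of 3618 pairs of a named result and a setting, 3225 stayed past the threshold and 393 did not. Most of these pairs leave out 1 pool, often one outside the comparison, and some count a pool several times. Most named genes were also chosen for 1 sign in both sets. The share kept is therefore no measure of how firm a result is. At the steps other than into early and mid-microspores, 3 of 21 named calls stayed from direct slides. With these slides turned by the dyes, as first planned, 71 of 99 named results stayed, 19 lost the threshold and 9 changed sign without passing: lox2 (-0.12), adh1 (-0.040), MADS5 (-0.042), cesa10 (-0.24), ec2e (0.19), glu1 (0.013), cc7 (0.068) and LDH (0.19) in the floret average, and cyp10 (-0.086) in mid-microspores. Among the other alternatives fixed in advance, the stage effect in upper florets stayed within 1.5 times its count throughout, and that in lower florets and the floret average did except with slides as replicates. The 17 floret differences at single stages became 33 with the low scan, with the smallest of the 3 scans' p-values and with scaled columns, and 84 with the median of the scans, and the interaction count of 0 became 1 with the low scan and with the smallest p-values. Scaled columns gave 1376 and 1507 first-to-last calls in upper and lower florets. Taking the slide as the replicate, which counts a pool several times, gave 7100 for the stage effect in lower florets, 5556 and 5502 first to last, 5218 and 5818 for neighbouring stages, 7193 and 5809 for florets at each stage and on average, and 2512 for the interaction. Direct slides only, which use fewer slides, gave 314 and 394 for neighbouring stages. Without the replicate block, 99 floret differences passed at single stages; whether pools of one number share further deviations cannot be read from values that are relative to the mean of their set. Floret slides turned by the dyes gave 2436 and 2560 for neighbouring stages, 0 for florets at each stage and 1 on average. Leaving out the most repeated values, chosen after seeing the data, gave 10 at each stage. The fold of 28 of 99 named results shrank by more than 1.5 times with the median of the scans. This count leaves out values given for list members alone, some of which shrank as well. Of 11 tests of the first lists past the threshold, 11, 10 and 2 stayed with the low, medium and high scan, and of 13 of the added lists 13, 12 and 12; by camera with an estimated correlation 0 of either did. Leaving out 1 pool, where the lone pool is assumed to vary like the other groups, gave 3592 to 4566 and 3586 to 4575 for the stage effects, 1770 to 3273 and 2016 to 3415 first to last, 346 to 1147 and 478 to 1391 for neighbouring stages, 0 to 55 for florets at each stage, 2600 to 3264 on average and 0 to 6 for the interaction, in upper and lower florets where 2 ranges are given. Fewer pools leave fewer values per test; for the other changes, and for counts that rose without a pool, the cause was not tested. The spread between pools limits what can be called: 38.8% of simulated 2-fold changes were called from the first to the last stage in upper florets. That simulation changed 200 of 12160 features, and the share called also depends on how many change. In the real comparison 3246 features were called, so the share called there may differ.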

Other observations

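The lists named here were written after the feature names had been seen, the early microspore pattern was noticed in the results, and the tests of floret differences against the dye effect and between the sets were chosen after those results were seen.

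Aquaporin genes rose from meiocytes to mid/late microspores, 12 of 25 features in upper florets and 11 in lower florets with 0 falling by limma (13 and 12 when adjusted over the list alone; adjusted p = 6.23e-04 and 0.00115, and adjusted p = 0.459 with an estimated correlation for both). Cysteine proteases and cystatins rose as well, 7 and 6 of 10 features (7 and 7 when adjusted over the list alone; adjusted p = 9.32e-04 and 0.00222, and adjusted p = 0.0753 with an estimated correlation for both), with cpi2 at 1.37 and 1.52. Ribosomal protein genes fell, 12 and 11 of 30 features with 1 rising in each floret (15 and 15 when adjusted over the list alone; adjusted p = 0.00198 and 9.32e-04, and adjusted p = 0.459 with an estimated correlation for both), among them rps10 (-1.16 and -1.03) and rps28 (-1.02 and -1.07). Light harvesting, photosystem and Rubisco genes, which overlap the photosynthesis list, rose in 10 and 11 of 18 features and fell in 2 of each (adjusted p = 0.0261 and 0.0112, and adjusted p = 0.577 with an estimated correlation), and were lower in upper than in lower florets in 7 features and higher in 1 (adjusted p = 0.0490, and adjusted p = 0.577 with an estimated correlation), a result that did not pass with the medium (0.0554) or the high scan alone (0.0607). Cellulose synthases rose in 8 of 11 features in lower florets (adjusted p = 0.00115, and adjusted p = 0.459 with an estimated correlation) and in 3 in upper florets (0.0613). Phenylpropanoid genes rose in 7 of 17 features and fell in 1 in upper florets (adjusted p = 0.00808, and adjusted p = 0.459 with an estimated correlation), with PAL1 at 1.43 and 1.37, and rose in 7 in lower florets (0.0795).

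Between florets, 8 of 25 DNA replication features were lower in upper florets and 1 was higher (adjusted p = 0.00563, and adjusted p = 0.0753 with an estimated correlation), with mad2 at -0.69 and pcna2 at -0.50 and -0.44. Histone genes were lower in 4 of 22 features (adjusted p = 0.00344, and adjusted p = 0.459 with an estimated correlation). These 2 lists did not pass from the first to the last stage (adjusted p = 0.533 and 0.657 for DNA replication and 0.0837 and 0.652 for histones, in upper and lower florets). In the 3 comparisons, in the order upper florets, lower florets and floret average, adjusted p-values were 0.564, 0.870 and 0.707 for jasmonate genes, 0.548, 0.269 and 0.587 for glutathione transferases, 0.657, 0.707 and 0.213 for antioxidant enzymes, 0.302, 0.270 and 0.798 for folding in the endoplasmic reticulum, 0.213, 0.336 and 0.270 for glycolysis, and 0.894, 0.764 and 0.0856 for MADS box genes. The floret averages of ribosomal proteins (0.670), cellulose synthases (0.657), aquaporins (0.381), phenylpropanoid genes (0.712) and cysteine proteases (0.548) did not pass.

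A group of features rose into early microspores and fell after. In both florets 65 features rose from tetrads to early microspores and fell to mid-microspores (82 in upper and 117 in lower florets; 0.789 for independent lists), and 5 fell and then rose. Among them were 5 of the features of ss2, the mitochondrial porin gene vdac2 (2.40 and -2.25 in upper, 3.23 and -3.40 in lower florets), GRF14 (0.83 and -0.93, 1.33 and -1.46), GNAT42, sm2 and AN13, and among those that dipped the proton pump gene H+-PPase (-0.95 and 0.89, -1.09 and 0.74). The 2 changes share the early microspore pools, so a deviation of these pools alone would favour the pattern.

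The sign of the stage ratios, on which that of the floret ratios depends, is likely Cy5 over Cy3. This rests only on the medians of 4 meiosis features (-1.04 in upper and -0.91 in lower florets), of which 2 passed in lower florets.

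Floret averages differed for 3252 features, while 17 differed at single stages. When upper and lower labels were exchanged at random within stages and sets, 1 of 100 exchanges, the real one, gave as many features. The highest other gave 277 and their median was 0. This argues against a chance split of the labels, though 100 exchanges cannot show a share below 1 in 100. The exchanges take the floret slides as deposited, and with those slides turned by the dyes 1 feature passed. The dye effect of the stage slides had r = 0.238 with the mean of the floret slides whose upper pool carried Cy5 and r = -0.327 with the others. A dye effect shared by slides that hold Cy5 over Cy3 would give r of 1 sign. These r repeat the ones from which the floret slides were read as deposited, so they are no separate support for the floret difference. The floret average was not related to the first-to-last change, as it would be if upper florets were further along at all stages (r = 0.0230). This r could miss a lead at some stages only, or along steps that rise and then fall, so it does not decide that question. The 2 sets had r = 0.619, which argues against a difference in 1 set alone. A handling or amplification batch shared by the upper pools of both sets stays open, since the design confounds it with floret, and a lasting difference between florets is a candidate explanation beside it.

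Few features changed between meiocytes, dyads/tetrads and tetrads. If the mixed dyad/tetrad pools had split 1 step as large as the next, tetrads against meiocytes would approach that next step. But 177 and 149 features were called there in upper and lower florets, against 779 and 697 from tetrads to early microspores when each is adjusted alone. That argues against the mixture as the whole cause of the gap to the next step. The single steps had 55 and 17 features in upper and 27 and 98 in lower florets, adjusted together, so a smaller step may still have been split. Changes in a minor cell type may be diluted in whole anthers, which was not tested.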
